A study of Homo sapiens and Mus musculus with 14 samples.

How the data were processed

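ATAC-seq, which marks accessible DNA by transposase insertion, was recorded for 14 samples of 2 established cancer cell lines. MDA-MB-436, a human breast adenocarcinoma line, gave 8 libraries: 3 of control cells, 3 of SMARCAL1 knockout clone 1 and 2 of SMARCAL1 knockout clone 2. Per the labels, the control and clone 1 libraries belong to batch 1 and the clone 2 libraries to batch 2, and the replicates are biological. The 6 libraries of B16F10, a mouse melanoma line, are 3 of Smarcal1 knockout cells and 3 of reconstituted cells, and they were not analysed here.

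The data used were 3 peak lists, one for each MDA-MB-436 group, in which the authors had already merged the peaks of the replicates, per the labels. Each deposited line holds a chromosome, a start, an end and a score. Per the submitters' processing notes, HISAT2, MACS2 and ChIPseeker were used with the builds hg38 and mm10; versions and settings are not given in the sources used here. The contig names in the deposited lists are those of hg38. The deposited coordinates were counted from 0 and are printed here counted from 1.

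The lists have no header, so the unit of the deposited score was settled from its values. The most frequent scores of each list equal −log10 of the upper tail of a Poisson distribution at successive whole pileups, for 1 constant background per series. Series with at least 500 peaks and at least 4 steps were kept. There were as many as libraries, 3, 3 and 2, and each series was taken as 1 library. The smallest, in clone 1, had 553 peaks on 4 steps, so the match in number may depend on these cutoffs. The deposited score is therefore read as the −log10 p of the authors' peak caller. No score lies below 5 in any list. Scores with more decimals than a single call carries are means over merged peaks of several replicates. Single calls had 5 decimals in both batch 1 lists and 6 significant digits in the batch 2 list, so the output format differed between the batches. Only part of the means can be recognised in this way. Scores were used to describe, rank or filter peaks within a list.

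The background of a series depends on the depth of its library and on the length to which the peak caller extended each read. The narrowest peak on each series served as an upper limit of that length, and the background per 100 bp of it as a relative depth. Read totals were not used here. This relative depth assumes the same genome size setting in every call.

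Gene positions came from a RefSeq table of assembly GRCh38.p14, whose primary chromosomes have the hg38 coordinates. It held 19974 protein-coding genes on the primary chromosomes, with start and end but no strand. The planned promoter class, within 1000 bp of a transcription start site, could therefore not be built. It was replaced by gene-end peaks, which lie within 1000 bp of either annotated end of a protein-coding gene, so peaks at the 3′ ends of genes are included. The planned comparison of AP-1 motifs in distal peaks was not run, since no genome sequence was used here.

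A peak counted as found in another list when at least 1 bp overlapped. Shares of peaks carry exact binomial 95% intervals, which cover counting error only. With 1 merged list per group there is no replicate test, and no p-value is given for any comparison. Control peaks absent in both clones were counted beside 3 expectations: the product of the single shares, and 1000 draws of independent losses within control score deciles or within finer strata. The finer strata combined score decile, width, gene-end position and whether the score was a mean. Peaks found in both clones and not in control were counted beside 100 draws in which the clone 2 peaks were moved along each chromosome. Ranges given with draws are the lowest and highest draw, not 95% intervals. Gene-level counts used the presence of any peak within 1000 bp of a gene end.

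In windows of 5 Mb with at least 40 control peaks, and on each chromosome, the number of control peaks found in a clone was divided by the number expected from their score deciles. For 17 gene lists written before the data were examined, the share of members losing their gene-end peak was placed among 10000 random gene sets of the same size, matched on the decile of the control gene-end score. Ties were split evenly in the percentile. Of 399 list entries, 1 had no match in the gene table.

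The genes named in the text followed a rule written before the data were examined. It took CD274 and SMARCAL1; the 10 genes with the strongest control gene-end peak and none in either clone; the 10 genes with a gene-end peak in both clones and none in control that came first by the lower of their score ranks in the clones; the 5 genes with the most control peaks absent in both clones in the gene body plus 10 kb on each side; and members of the nucleic acid sensing, checkpoint ligand and AP-1 factor lists that lost or gained a gene-end peak in both clones. Not every gene that the rule takes is reported here. Other members of the lists are named as examples and were chosen after their values were seen.

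Overlap counts were tested on simulated lists made from the 64806 control peaks. Every kept peak was found again after shifts of up to 40 bp, 99.9% of removed peaks were counted as absent, and counts differed by 0 from those of bedtools. The placing of gene lists was tested on 12000 simulated genes with lists of 25 members. Of 100 such lists without an effect, 9 fell outside the central 95% of random sets, and of 100 lists with 30 points more absence, 90 lay above it. The alternatives tried were other overlap rules, the peaks above the median score of each list, lists of equal length, merged neighbouring peaks, autosomes only, other gene-end and locus windows, equal weight for score deciles and unmatched random sets. Analyses used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1.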

Results

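Accessible regions were compared between control MDA-MB-436 cells and cells of 2 SMARCAL1 knockout clones. SMARCAL1 is a DNA translocase that remodels stalled replication forks, and the series concerns its part in innate immune signalling and in the expression of PD-L1, the checkpoint ligand encoded by CD274. The control list, merged from 3 libraries, held 64806 peaks covering 33.2 Mb with a median width of 399 bp. The clone 1 list, from 3 libraries of the same batch, held 39537 peaks covering 22.3 Mb with a median width of 453 bp. The clone 2 list, from 2 libraries of batch 2, held 34572 peaks covering 8.37 Mb with a median width of 200 bp. Gene-end peaks, which lie within 1000 bp of either end of a protein-coding gene, made up 19.0%, 24.7% and 27.4% of the control, clone 1 and clone 2 peaks, while gene-end windows cover 2.40% of the gene-bearing span.

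The depth of the libraries is known only through the scores, which are the authors' −log10 p values. The background recovered from them, per 100 bp of the narrowest peak, was 1.49 to 1.76 in the 3 control libraries, 1.47 to 1.98 in the 3 clone 1 libraries, and 0.676 and 0.904 in the clone 2 libraries. The lowest pileup recovered on a series was 5.44 to 5.59 times the background in control, 4.22 to 5.76 times in clone 1, and 8.12 and 12.4 times in clone 2. The value of 12.4 belongs to a score of 7.11, above the clone 2 list minimum of 5.01, so lower pileups called there may have been missed. Each group is 1 merged list, so no difference below has a replicate check, and all intervals cover counting error only.

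The comparison of control with clone 1, both of batch 1, asked which accessible regions of control cells were missing in a SMARCAL1 knockout clone. In 1 clone, SMARCAL1 loss cannot be told apart from other differences between that clone and the control cells. Of 12166 protein-coding genes with a gene-end peak in control, 2561 (21.1%) had none in clone 1. The retained genes included CGAS and TBK1, a DNA sensor and the kinase of the same pathway, and JUN, a transcription factor of the AP-1 family. The genes without a clone 1 peak included TREX1, a cytosolic DNA exonuclease, MRE11, a double-strand break nuclease, and ATRX, a chromatin remodeller. Their control scores were 5.12, 7.56 and 6.76. All of these had a gene-end peak in clone 2, MRE11 with a score of 18.2 and ATRX with 14.9. The shares absent in clone 1 were 7 of 18 nucleic acid sensing genes (87.1 percentile of matched random sets), STING1, IKBKE and IRF7 among them, 3 of 14 AP-1 factors (25), 4 of 28 replication fork and repair genes (85.6) and 4 of 27 chromatin remodellers (4.36). Among 7808 genes without a control gene-end peak, 463 had one in clone 1, among them IRF3, the factor activated by TBK1, with a score of 6.35.

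Over all regions, 37494 of 64806 control peaks (57.9%, 95% interval 57.5 to 58.2) had no overlapping clone 1 peak, and 12143 of 39537 clone 1 peaks (30.7%, 30.3 to 31.2) had no overlapping control peak. The absence followed peak strength. Clone 1 peaks were found over 7.38% of the control peaks in the weakest score decile and over 99.1% of those in the strongest. Gene-end peaks were retained more often than other peaks of like score. With equal weight for each score decile, 55.4% of gene-end and 39.2% of other control peaks were found in clone 1, a difference of 16.3 points (15.3 to 17.3). Peak width was not equalised in this or in later comparisons of gene-end with other peaks, and wider peaks can be overlapped more easily. Among control peaks scoring above the median the absent share was 32.0%, and among control peaks whose score was a recognisable mean over replicates it was 35.5%; with lists of equal length it was 38.1%. The share of clone 1 peaks absent in control was 12.5% above the median score and 5.12% among means.

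**Figure D1:**
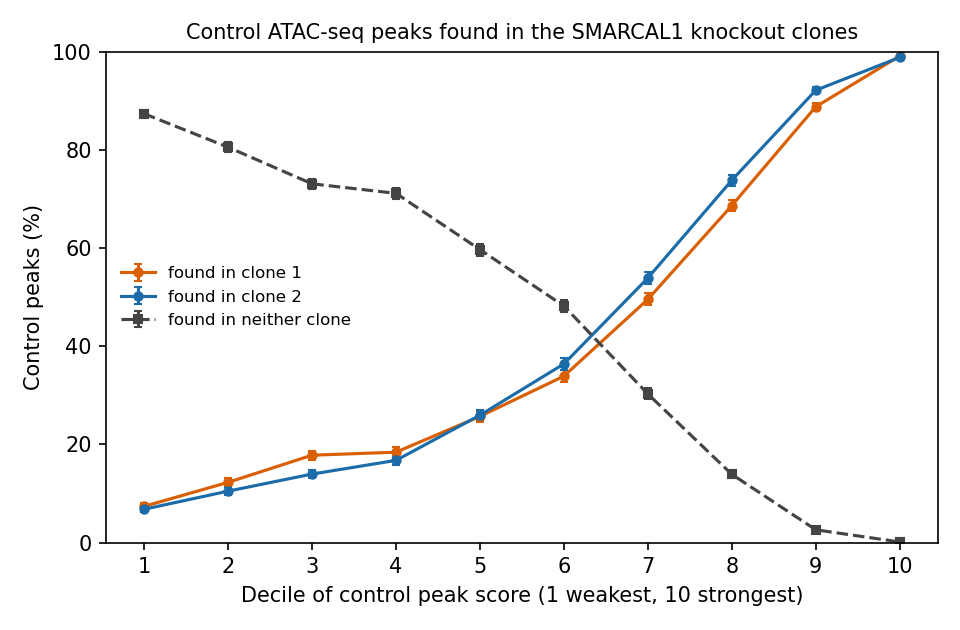
Share of control peaks (%, vertical axis) overlapped in clone 1, in clone 2 or in neither clone, by decile of the control peak score (horizontal axis, 1 weakest); bars are exact binomial 95% intervals. The share found rises from 7.38% to 99.1% in clone 1 and from 6.79% to 98.8% in clone 2.

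The comparison of control with clone 2 asked the same question of an independent clone, but the clone 2 libraries are of batch 2 and the control list is of batch 1, so clone and batch cannot be told apart. Of the 12166 genes with a control gene-end peak, 3663 (30.1%) had none in clone 2. These included FOS, FOSL1 and FOSL2 of the AP-1 family, the NF-kB subunits RELA and NFKB2, the remodelling subunits ARID1A and PBRM1, and MAVS, the adaptor of RNA sensing, each of which had a gene-end peak in clone 1. The shares absent in clone 2 were within the range of matched random sets for these lists: 6 of 14 AP-1 factors (61.2 percentile), 7 of 18 NF-kB pathway genes (88.8), 10 of 27 chromatin remodellers (48.2) and 7 of 18 nucleic acid sensing genes (45.6). TREX1 and the AP-1 factor BATF3 had a peak in clone 2 and none in clone 1. Among the 7808 genes without a control gene-end peak, 121 had one in clone 2.

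Over all regions, 37014 control peaks (57.1%, 56.7 to 57.5) had no overlapping clone 2 peak, and 3831 of 34572 clone 2 peaks (11.1%, 10.8 to 11.4) had no overlapping control peak. Requiring an overlap of at least 50% of the control peak raised the absent share to 86.0%. Control peaks found in both clones had a median width of 716 bp, and clone 2 peaks found in both other lists 241.5 bp. Narrow clone 2 peaks often cannot cover 50% of a control peak, so the 86.0% does not by itself show lost accessibility. The absent share was 29.0% among control peaks scoring above the median, 31.5% with lists of equal length and 33.6% among recognisable means. The share of clone 2 peaks absent in control was 23.3% with lists of equal length, 4.92% above the median score and 4.26% among means. Clone 2 lacked relatively more control peaks on several gene-rich chromosomes. The number found relative to that expected from score deciles was 0.618 on chromosome 22, 0.766 on chromosome 17 and 0.802 on chromosome 19, against 1.19 on chromosome X and 1.16 on chromosome 18. The same ratio in clone 1 was 1.06, 1.07 and 1.18 on chromosomes 22, 17 and 19.

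**Figure D2:**
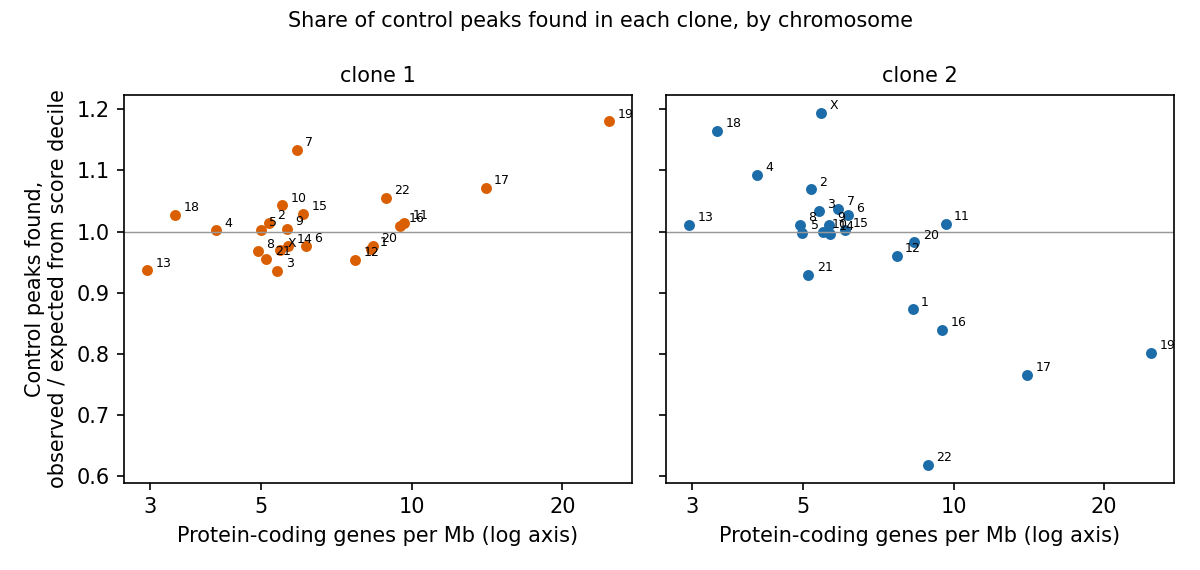
Control peaks found in each clone divided by the number expected from their score deciles (vertical axis), by protein-coding genes per Mb of chromosome (horizontal log axis), 1 point per chromosome. Chromosome 19 lies at 1.18 in clone 1 and at 0.802 in clone 2, and chromosome 22 lies lowest in clone 2, at 0.618.

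Regions that differed from control in the same way in both clones were examined next. Of the 12166 genes with a control gene-end peak, 7877 (64.7%) had one in both clones and 1935 (15.9%) had none in either. The genes without a peak in either clone included 6 of 18 nucleic acid sensing genes: ADAR, which edits double-stranded RNA, DHX58, IKBKE, IRF7, RNASEH2A and STING1, the adaptor downstream of CGAS. They also included the checkpoint ligands CD276, CD70, HHLA2 and PVR, 4 of 12, and the AP-1 factors JUNB and BATF2, 2 of 14. The control scores of these 12 genes lay between 5.03 and 7.35, against a median of 6.26 and a minimum of 5 over all control peaks. BRCA1, a homologous recombination gene, was the 1 DNA repair gene with a gene-end peak in both clones and none in control, at scores of 6.15 in clone 1 and 6.33 in clone 2.

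The 10 genes with the strongest control gene-end peaks and none in either clone were GSTO1, EIF4EBP2, SEMA4C, IRX5, MAP7D3, C18orf63, SYT2, EFNA5, ZNF608 and KIF26B, with control scores from 21.2 to 11.4. In 7 of the 10 the control peak was overlapped by a clone peak that lay outside the gene-end window. The exceptions were EIF4EBP2 (chromosome 10, 70404145 to 70428618), which encodes a repressor of cap-dependent translation, SYT2 (chromosome 1, 202590596 to 202710454), a synaptic vesicle calcium sensor, and ZNF608 (chromosome 5, 124636915 to 124748824), a zinc finger gene. Their control scores were 14.5, 12.1 and 11.7. When any clone peak over a control gene-end peak was also counted, 1853 genes were left without one in either clone.

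A gene-end peak present in both clones and not in control was found at 44 genes. Ranked by the lower of their score ranks in the clones, the first included C2CD4B, RAB38, YAE1, SCP2, TMEM63C, B3GNT5, H3C12, MAP3K6 and MRPS2. C2CD4B (chromosome 15, 62163535 to 62165285) had scores of 7.47 in clone 1 and 11.4 in clone 2, and RAB38 (chromosome 11, 87803715 to 88175443), a GTPase of melanosome biogenesis, had 6.91 and 10.2. The highest single scores were those of ECH1 in clone 1 (7.70) and NOL10 in clone 2 (15.5), genes outside the naming rule that were picked after their values were seen. At 43 of the 44 genes the clone peaks overlapped no control peak anywhere.

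Over all regions, 30248 control peaks (46.7%, 46.3 to 47.1) were absent in both clones and 20546 (31.7%) were found in both. The share absent in both was 19.0% above the median score, 22.4% with lists of equal length and 21.2% among means. Independent lists would share 21415 absent peaks, independent losses within score deciles 28062 (27755 to 28378), and independent losses within finer strata 28888 (28587 to 29244). Both comparisons use the same control list, so part of the excess may come from control peaks that are not reproducible. Of the peaks absent in both, 79.6% scored below the median of the control list, and 177 of the 12961 control peaks in the upper 2 deciles (1.37%) were absent in both. On the primary chromosomes, 574 of 11786 clone 1 peaks absent in control (4.87%) overlapped a clone 2 peak that was also absent in control, against 6.86 (2 to 12) when the clone 2 peaks were moved. In the other direction it was 586 of 3765 clone 2 peaks (15.6%). Moved peaks could land at any position, also where no list had peaks. The draws therefore cannot tell a shared gain from open sites that the control calls missed. Clone 1 peaks found in clone 2 and not in control had a median score of 5.72, against 6.07 over the clone 1 list.

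Gene-end peaks made up 8.88% (8.55 to 9.21) of the control peaks absent in both clones and 34.4% (33.8 to 35.1) of those found in both, a difference of -25.5 points (-26.3 to -24.8). With equal weight for each control score decile the difference was -12.6 points (-15.2 to -10.0). Width was not equalised: the median was 255 bp for control peaks absent in both clones and 716 bp for those found in both. The 5 genes with the most control peaks absent in both clones were DLG2 with 35 of 79, DAB1 with 33 of 46, CDH12 with 32 of 49, AGBL4 with 30 of 48 and CDH18 with 28 of 39. The shortest of the 5, CDH12, is 1103 kb long. DLG2 encodes a synaptic scaffold protein, and CDH12 and CDH18 encode cadherins.

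Among the 17 gene lists, the interferon-stimulated genes had the highest percentile for absence in both clones. Of 21 members with a control gene-end peak, 8 (38.1%) had none in either clone: IFI44L, IFIT5, IFITM3, ISG20, LGALS3BP, OAS3, OASL and PARP14. That share stood at the 97.6 percentile of matched random sets, with ties split evenly, and equalled the upper limit of their central 95%, also 38.1%. No other list had a percentile beyond that range. Chance alone would give about 1 of 17 lists such a percentile, and under 3 other settings the percentile was within the range. The share was 31.6% (87.9 percentile) with gene ends taken within 500 bp and 13.6% (14.2 percentile) within 3000 bp. It was 33.3% (94.0 percentile) when clone peaks over a control gene-end peak were also counted, which gave OASL a peak in clone 1. The nucleic acid sensing list, at 33.3%, stood at the 88.6 percentile, the checkpoint ligands, at 33.3%, at the 76.0 percentile and the AP-1 factors, at 14.3%, at the 22.9 percentile.

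The remaining lists were also within the range of random sets. Gene-end peaks were absent in both clones at 6 of 14 mesenchymal genes, including AXL and SNAI1, at 4 of 20 AP-1 target genes, including CCND1 and CD44, and at 3 of 28 replication fork and repair genes, namely ATRIP, FANCA and FANCD2. They were absent at 3 of 27 chromatin remodellers (CHD3, CHD4 and SMARCB1), at 2 of 18 NF-kB pathway genes, at 1 of 23 cell cycle genes and at 1 of 25 housekeeping genes. Of the breast epithelial lists, 2 of 11 basal genes and 2 of 7 luminal genes had none; the latter, KRT8 and KRT18, are neighbours that share 1 control peak. Antigen presentation lost 1 of 8 members, CALR; the HLA genes had no control gene-end peak, and peaks there are uncertain because hg38 carries alternative contigs for this region. Markers of cells not cultured here gave 3 of 7 for leukocytes (5 of 7 in clone 1 alone, at the 98.5 percentile), 1 of 4 for melanocytes, and 1 of 4 for endothelial cells and fibroblasts.

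**Figure D3:**
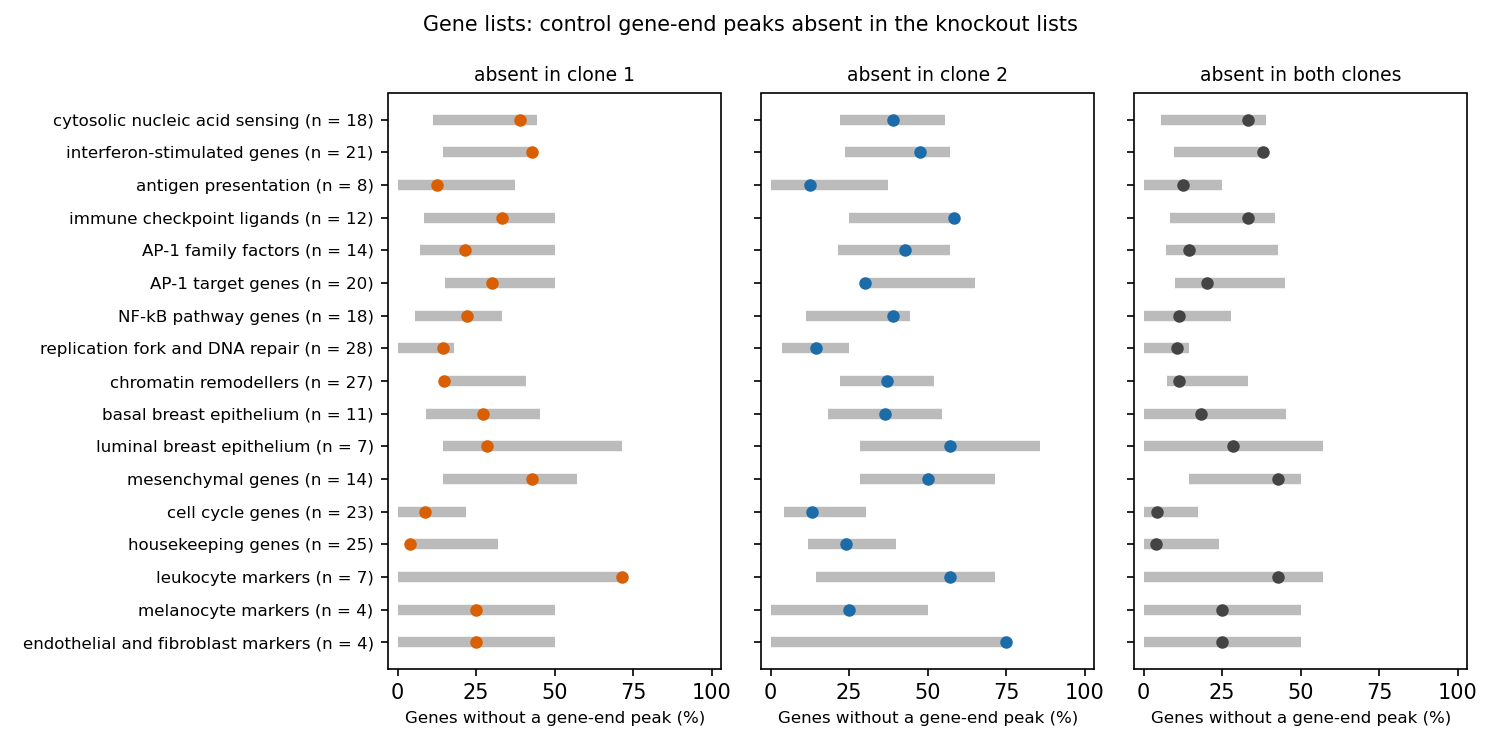
Genes with a control gene-end peak and none in clone 1, in clone 2 or in both (points, %, horizontal axes), for each of 17 gene lists with the number of genes n; grey bars span the central 95% of 10000 matched random sets. The interferon-stimulated genes lie at 38.1% for both clones, at the upper edge of their bar.

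CD274 was examined as the gene for PD-L1, in the gene (chromosome 9, 5450542 to 5470554, hg38) and 50 kb on each side. The peak at the first annotated base of CD274 (5450318 to 5450905 in control) was present in all 3 lists, with scores of 15.4 in control, 9.51 in clone 1 and 19.5 in clone 2. A peak 12.4 kb to its left, inside PLGRKT (5437156 to 5438130), was also in all 3 lists, at 18.5, 8.96 and 25.3, as was a peak next to PDCD1LG2, the gene for PD-L2 (5509407 to 5510175), at 16.7, 6.66 and 17.9. A weaker peak inside CD274 (5455316 to 5455499) had scores of 5.90, 5.35 and 7.46. The control list held 3 more peaks, with scores of 5.19 to 7.20, that neither clone had, so the window held 7, 4 and 4 peaks. Scores depend on the depth and settings of each call and are not compared between lists. Among the 34572 strongest control peaks, as many as the clone 2 list holds, the window had 4. These include the peak at 7.20, which neither clone had, and lack the one at 5.90, which both clones had. Control peaks scoring within 10% of the 3 absent peaks (5.19, 5.44 and 7.20) were found in clone 1 at 13.6%, 14.8% and 44.2%. In clone 2 these shares were 11.4%, 13.3% and 48.4%.

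**Figure D4:**
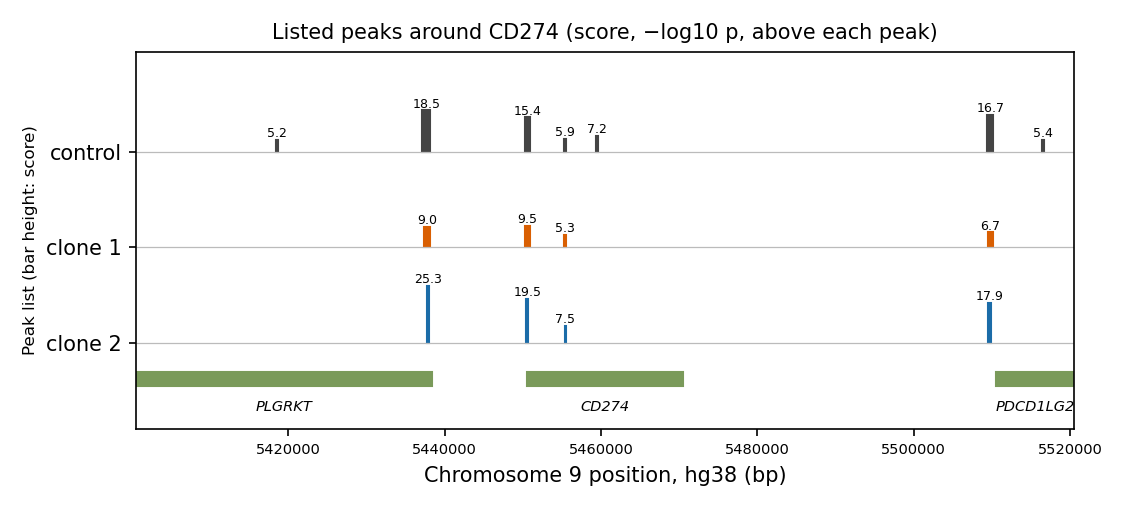
Peaks of the control, clone 1 and clone 2 lists around CD274 on chromosome 9 (horizontal axis, hg38 position in bp); bar height and the number above each bar are the −log10 p score within that list, and green boxes are genes. The 4 peaks of each clone all overlap control peaks, and scores are not comparable between the lists.

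SMARCAL1 itself (chromosome 2, 216412484 to 216483053) had a peak across its first annotated base in all 3 lists, with scores of 16.7 in control, 13.1 in clone 1 and 13.5 in clone 2. The gene and 50 kb on each side held 10 control, 8 clone 1 and 7 clone 2 peaks. A peak list does not show whether the gene is disrupted, so this does not check the knockout.

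The clones differed from each other in where control peaks were missing. Of control peaks absent in clone 1 and found in clone 2, 9.80% (9.12 to 10.5) were gene-end peaks, against 27% (25.9 to 28.1) of those absent in clone 2 and found in clone 1. At equal weight per score decile, gene-end peaks were found in clone 2 at 44.0% and other peaks at 43%, a difference of 1.03 points (0.197 to 1.86) against the 16.3 points in clone 1. The gap between the clones was 15.2 points (SE 0.659, counting error only).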

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

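The tests of this part were chosen after the results were seen, except that of gene-dense regions, whose prediction was written before its value was computed. Over 556 windows of 5 Mb, the share of control peaks found relative to that expected from score deciles had a Spearman correlation with the number of protein-coding genes of 0.201 in clone 1 and of -0.564 in clone 2. The opposite signs of the clones, each a single list, drew attention to this result; the difference was not tested. The lowest clone 2 windows include chromosome 17 from 40000001 to 45000000, where 9 of 106 control peaks were found against 28.6 expected.

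Gene-end peaks were found more often in clone 1 (72.3%) than in clone 2 (64.0%), and other control peaks less often (34.9% against 38.5%). The gap between the clones is the difference between their gene-end minus other found shares, so both kinds of peak enter it. This gap was 11.9 points unweighted and 15.2 points with equal weight for each score decile, so it did not shrink. Both clones were scored on the same control peaks, and the share found rose with score alike in both. The weighting therefore cannot decide whether control peak strength plays a part. A loss of gene-dense regions as a whole from the clone 2 list is argued against as the full cause, since the gap was 12.2 points (SE 0.855) with equal weight also for each of 5 classes of windows by gene count, and 9.09 points in the most gene-dense class. A difference between library batches cannot be told apart from the clone, because 0 control lists of batch 2 were analysed here. GC content, which may differ between gene ends and other regions, was not tested, and a biological difference between the clones stays open as untested.

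The control peaks absent in both clones made up 46.7% of the list. Loss of chromosome segments in clone 1 that lowers the found share below 0.75 times the expected is argued against as the main source. Only 2.45% of these peaks lay in such windows, 17 in number, and in clone 2 it was 16.6%, in 73 windows. Loss of some copies of a segment may not reach that cut and was not tested. The SD of the clone 1 ratio over windows was 0.144, against 0.0968 from counting. Lower sequencing depth of the clone 1 libraries stays open: their background per 100 bp of the narrowest peak was 1.03 times that of control on average, but 0.935 times without the highest of the 3, and the lowest lay below every control library. The clone 2 libraries had 0.487 times the control background, and 79.6% of the absent peaks scored below the control median, so lower depth in clone 2 and peaks near the calling threshold may each account for part of the pattern. Signal over background within peaks was not tested, and an effect of SMARCAL1 loss on weak distal regions remains open beside it.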

How the results depend on the processing

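Tests on recognisable means over replicates, and the count of clone peaks that overlap a control gene-end peak, were added after seeing the data; the other alternatives were planned. In the order absent in clone 1, in clone 2 and in both clones (of control peaks), then absent in control (of clone 1 and of clone 2 peaks), the reported shares were 57.9%, 57.1%, 46.7%, 30.7% and 11.1%. Overlap of at least 50% gave 61.8%, 86.0%, 58.0%, 33.2% and an unmoved last share; any peak within 500 bp gave 55.5%, 55.7%, 44.3%, 28.3% and 10.4%. Peaks above the median score of each tested list gave 32.0%, 29.0%, 19.0%, 12.5% and 4.92%; lists of equal length gave 38.1%, 31.5%, 22.4%, 37.4% and 23.3%. Merging peaks closer than 500 bp gave 57.5%, 55.8%, 46.1%, an unmoved clone 1 share and 11.7%, and autosomes alone moved none of the 5 beyond its interval. Recognisable means gave 35.5%, 33.6%, 21.2%, 5.12% and 4.26%. The gene-end difference of -25.5 points stayed negative: -26.4 within 500 bp and -23.3 within 3000 bp of gene ends, -12.6 with equal weight per decile, -26.7 with any peak within 500 bp, -24.0 above the median score and -19.6 among means. The control CD274 count of 7 became 4 with 20 kb on each side and 4 with equal lengths; the clone counts stayed within 1.5 times. The number of gene lists with a percentile beyond the central 95% for absence in both clones, 1 as reported, was 0 with gene ends within 500 bp, 0 within 3000 bp, 0 with overlapping clone peaks counted, 2 without matching and 1 with equal lengths. Of 68 shares of single gene lists for absence in both clones, under the settings that can move them, 63 stayed in range and 5 moved. The range is the central 95% of the matched random sets of the reported setting, not closeness to the reported share. It is wide: the interferon-stimulated share of 13.6% within 3000 bp, against 38.1% as reported, counts as in range. The cause was not tested where a share moved, except that fewer weak peaks enter the sets above the median and the lists of equal length. Peak widths also limit the 50% rule, since clone 2 peaks are narrower than control peaks. No paired analysis was possible because the replicates of each group are merged into 1 list, which also kept replicates from being left out in turn. The AP-1 motif comparison and its 5 alternatives were not run.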

Other observations

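Of the 10 strongest control peaks that neither clone had, 5 overlapped a protein-coding gene; the regions named here were picked by score after the lists were compared. The highest score, 15.2, was inside TBC1D5 (chromosome 3, 17686725 to 17686970), a gene of endosomal trafficking, followed by 14.5 at EIF4EBP2 and 14.2 at a region 3.62 kb from the olfactory receptor gene OR5A2 (chromosome 11, 59430030 to 59430233). Peaks inside GUCY2F and ACSL4, a regulator of lipid peroxidation, both on chromosome X, were also among the 10, at 13.2 and 13.1. A further ACSL4 peak (109733065 to 109733828, score 16.4) was absent in clone 1 and present in clone 2. On chromosome X, windows from 105000001 to 110000000 and from 145000001 to 150000000 were among the lowest in clone 1, with 11 of 42 and 22 of 92 control peaks found against 18.5 and 38.1 expected.

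Among regions present in both clones and not in control, a peak 31.7 kb from IMPG1 on chromosome 6 ranked among the 10 strongest in each clone, with scores of 10.6 in clone 1 (76104409 to 76104869) and 18.2 in clone 2. Other strong shared regions lay inside MAP2, a neuronal microtubule gene (chromosome 2, 209719037 to 209719366), inside SEMA3D (chromosome 7, 85104482 to 85104707, clone 2 score 17.3) and inside COL21A1 (chromosome 6, 56370064 to 56370445, clone 1 score 9.61). Clone 2 lacked 3 control peaks on chromosome 7 between 63753621 and 63760566 that clone 1 had, with control scores of 24.2, 23.5 and 23.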
